A study of Mus musculus with 196 samples.

How the data were processed

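The deposited table gives gene levels as RPM (reads per 1000000 reads assigned to endogenous genes), computed by the authors, for 25706 endogenous genes and 3 transgene rows. In columns where the transgene rows lift the total furthest above that sum the values are a signal on the same RPM scale, as deposited by the authors. The samples were mouse PGCLCs of 7 lines or clones and germ cells of embryos at E9.5, E14.5 and E15.5. Per the labels, cDNA of 3' ends was amplified from 1 ng of total RNA and sequenced on a NextSeq 500. Per the submitters' processing notes, cutadapt 1.9.1, TopHat2 2.1.0, Bowtie 1.1.2, SAMtools 1.3 and HTSeq 0.9.1 were used with genome build mm10, and the role of each tool and the gene annotation are not stated. Reads carried no stated molecular identifiers, so amplified copies could not be removed, and floors set in reads cover counting error only.

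Of 195 value columns 194 were matched to the 196 labelled samples and used, 1 column matched no sample and was not used, and 2 samples had no column (an H18 sample with B2RA at day 4 and an OE_A2 sample with DoxRA at day 7). In 3 lines of the table an extra empty cell had shifted the values, and these were realigned. The day of culture was taken from the sample titles, because the stage label of H18 reads day 3.5 for every sample. The labels give a pair of extraction protocols, with 22 libraries under the first and 172 under the second, and every PGCLC library of day 9 was made under the second. Whole read numbers were recovered from the step between values in each column, and 100 percent of values were whole reads within 0.05. Libraries held 877040 reads or more, 1 read was worth 0.192 to 1.14 RPM, and the largest share of one gene was 1.88 percent. By line, the lowest depth was 1472050 reads in H18, 939046 in OE_A2, 1821398 in OESko_A11, 1241239 in Sko_B6, 2090623 in Sko_F6, 985914 in Zko_E5, 877040 in Zko_G10 and 2798038 in the embryo.

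The comparisons, the tests, the gene lists and the alternatives were fixed before the data were examined, except for alternatives added later (an edgeR test on the recovered reads, a covariate for stroma, and list medians by day over the same members) and the tests that the closing section names as chosen after values had been seen. All p-values of genes are from limma 3.58.1 in R 4.3.3 unless edgeR is named. One limma model (lmFit, then eBayes with trend and robust settings) was fitted to log2(RPM + 1) of the 191 PGCLC libraries, with 1 mean for each of 98 groups of line or clone, treatment and day. Responses of a pair of clones were averaged with equal weight, and differences of responses were tested as contrasts. A gene was tested when at least 2 of the libraries compared reached 10 RPM, and was called at a Benjamini-Hochberg adjusted p under 0.05 with a change of at least 1 on the log2 scale. The count adjusted over a list alone used the same thresholds with the adjustment made over the tested members of that list. Lists with 3 or more tested members were tested by camera of limma with a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a comparison. The edgeR 4.0.16 quasi-likelihood test used TMM factors on 50 libraries in 25 groups.

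The 18 lists were early germ cell genes (14 members), germline genes silenced by methylation (21), meiotic prophase (41, of which Rec114 and Ankrd31 are not in the table), oocyte (28, Khdc3 not in the table), BMP response (15), RA response (20), pluripotency (20), mesoderm and endoderm (24), male prospermatogonia (16), feeder and stroma (20), gonadal soma (14), G2 and M phase (20), DNA replication (20), p53 and apoptosis (17), DNA methylation machinery (13, Dnmt3c not in the table), integrated stress response (16), cholesterol synthesis (20) and glycolysis (16). Genes named in the text were Zglp1 and Stra8, members of these lists, and in each comparison of day 9 the 6 largest rises and 6 largest falls among called genes with a mean of at least 20 RPM in the higher group and no overlap between the libraries of the groups. Overlap was not asked of differences of responses, and symbols of predicted genes, Rik clones and pseudogenes were counted but not named. The values of 1 gene that meets this rule are not reported here. Days 3.5, 4, 5 and 7 were described by lists, their members and counts. Athl1, the only gene called in its comparison, was named after its values were seen. Gene positions are from GENCODE mouse release 21 on mm10, where 361 of 366 genes named or listed had a position, and identifiers are those of the deposited table.

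A group with no read of a gene was given a floor of 3 reads over the group, and the fold against it is a lower bound. The embryonic libraries were compared with 10000 random gene lists matched on expression and by Pearson correlation over 10082 genes. Alternatives were pseudocounts of 0.5 and 5, no filter on low values, TMM factors, array weights, a term for replicate number, a fit of only the groups compared, single clones, each library left out in turn, edgeR and the stroma covariate. The steps were tested on simulated data with 200 changed genes added to libraries drawn at a dispersion of 0.0199. That value was the same for every gene and came from genes of at least 100 RPM. Real genes with more spread are called less often than these shares show. At 4-fold, 100 of 100 changes were called for Dox, 100 of 100 for BMP2 in the Zglp1 knockout and 96 of 100 for the difference of Dox responses with BMS. At 2-fold, which is the threshold itself, 37, 42 and 33 of 100 were called, and false calls numbered 1, 0 and 11. Of 20 simulated lists the 1 raised list was called and 0 of 19 unchanged lists were. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.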

Results

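Gene expression was measured by sequencing the 3' ends of RNA from mouse primordial germ cell-like cells (PGCLCs), which are made in culture from embryonic stem cells by way of epiblast-like cells and resemble early germ cells, and from 3 libraries of germ cells taken from embryos. The parent line, H18, carries fluorescent reporters of Prdm1 and Dppa3, both expressed in early germ cells. A pair of clones lacked Zglp1 (Zko_E5 and Zko_G10), a pair lacked Stra8 (Sko_B6 and Sko_F6), clone OE_A2 carried the Zglp1 coding sequence under a doxycycline-inducible promoter, and clone OESko_A11 carried that transgene on a Stra8 knockout background. Cells were sorted by reporter and expanded on feeder cells for up to 9 days with BMP2, retinoic acid (RA), both (B2RA), doxycycline (Dox), Dox with RA (DoxRA), or with compounds that the labels name only as BMS and WIN, the latter in medium without serum (SerumMinusWIN). H18 gave 27 libraries, OE_A2 64, OESko_A11 16, each Stra8 knockout clone 16 and each Zglp1 knockout clone 26. Groups held 2 libraries, except the serum-free medium without WIN (1 per day), the B2RA group of H18 at day 4 (1, the other having no column), and the embryonic stages (1 each). Libraries held 877040 to 5196593 reads and 11850 to 16957 detected genes. Replicate libraries correlated at 0.941 to 0.991 across genes and differed by more than counting error in all 93 pairs (chi-square per degree of freedom 1.62 to 59.9). The labels do not say whether replicates came from separate cultures. SE and p-values measured only the spread between libraries of the same group, which may be technical. Each clone had its own mean, so SE and p-values over a pair of clones held no spread between clones. Those p-values do not show that a change holds for other clones of the genotype. Levels are means in RPM ± SD, with n = 2 per group (n = 4 over a pair of clones) unless stated, and changes are differences of log2(RPM + 1) ± SE, a scale that understates the change of low genes.

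The targeted genes came first. Zglp1 (identifier 100009600; mm10 chromosome 9, 21062393 to 21067093, minus strand, protein coding) encodes a GATA-like zinc finger protein, and Stra8 (identifier 20899; chromosome 6, 34920163 to 34939344) a regulator of entry into meiosis. Tags of both genes remained in the knockout clones: at day 9 under B2RA, Zglp1 stood at 26.5 ± 8.76 RPM in Zko_E5 and 20.9 ± 6.56 in Zko_G10, against 51.2 ± 3.36 in H18, and Stra8 at 555 ± 187 RPM in Sko_B6 and 59.9 ± 10.1 in Sko_F6, against 731 ± 104 in H18. A 3' tag outside a deleted part checks nothing about the deletion, and the labels do not give the deleted part, so these levels neither checked nor contradicted the genotypes. The transgene carries the coding sequence of Zglp1 followed by mCherry, and its mRNA was read from the mCherry row: in OE_A2 at day 9 it rose from 284 ± 172 RPM to 1290 ± 519 with Dox, whereas the Zglp1 row stood at 6.65 ± 2.28 and 5.61 ± 0.642 RPM. PGCLC lines without the transgene held at most 2.08 RPM of mCherry tags. The reverse transactivator row stood at 14300 ± 1040 RPM in uninduced OE_A2 at day 9 and at 2390 ± 217 with Dox, 2620 ± 1150 with DoxRA, 2320 with SerumMinusWINDox and 2760 ± 428 with BMSDox. In OESko_A11 it stood at 12800 ± 4290 uninduced and 2730 ± 557 with DoxRA.

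**Figure D1:**
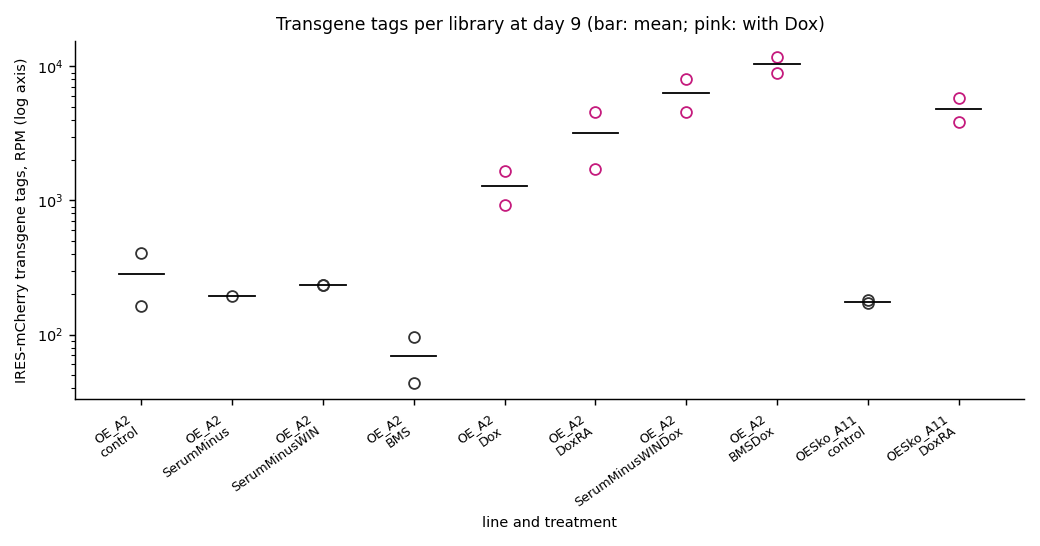
Tags of the IRES-mCherry transgene row at day 9 (RPM, log axis) in each library of OE_A2 and OESko_A11, by medium; points are libraries, bars are means, and groups with Dox are pink. Means ran from 69.7 RPM with BMS to 10300 RPM with BMS and Dox.

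Dox in OE_A2 asked what followed induction of the transgene in control medium. No line without the transgene was given Dox, so an effect of Dox itself could not be told apart from that of the transgene. At day 9 the meiotic prophase list rose: 34 of its 38 tested members rose and the other 4 did not pass (34 higher and 1 lower adjusted over the list alone), with a median change of 3.5. Prdm9, the histone methyltransferase that marks sites of meiotic recombination, rose from 4.42 ± 1.38 to 176 ± 36.6 RPM (5.04 ± 0.59, adjusted p = 2.4e-11), Msh4, a crossover factor, rose by 4.79 ± 0.46 (adjusted p = 1e-14), and Ccnb3, a cyclin of meiosis, by 4.82 ± 0.47 (adjusted p = 2.1e-14). The largest rise among the named genes was that of Adad1, a germ cell RNA-binding protein, from 1.41 ± 0.0428 to 110 ± 4.72 RPM (5.52 ± 0.50, adjusted p = 7.5e-16). Tex16 (5.33 ± 0.56) and Lypd4 (4.80) rose as well. Of 20 tested germline genes kept silent by promoter methylation in other cells, 19 rose (19 adjusted over the list alone), among them Tex101 (4.26), Taf7l (3.67), Mael (2.72) and Ddx4 (2.34). Of the oocyte list, Figla (4.40) and Nobox (3.54), transcription factors of early oocytes, and Ybx2 (1.5) rose, while Ooep (-1.63) and Tle6 (-1.10), of the maternal subcortical complex, fell, and the list as a whole did not pass (adjusted p = 0.2). Stra8 did not pass (0.85 ± 0.69, adjusted p = 0.36), at 594 ± 27.3 RPM against 332 ± 63.

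Glycolysis genes fell with Dox in OE_A2 at day 9: all 15 tested members passed (15 adjusted over the list alone), with a median of -3.11. Ldha (identifier 16828; chromosome 7, 46841475 to 46855627), the lactate dehydrogenase subunit, went from 982 ± 75.8 to 11.4 ± 2.77 RPM (-6.33 ± 0.77, adjusted p = 1.9e-10), and Pfkl, a phosphofructokinase, from 118 to 1.34 RPM (-5.70 ± 0.62). The lactate transporter Slc16a3 (-5.20), Upp1 (-4.92), Aire (-4.81) and the Nodal antagonist Lefty2 (-4.75 ± 0.66) were the other leading falls. Among 17 pluripotency genes 15 fell (16 adjusted over the list alone), including Tdgf1 (-4.49), Nanog (-2.70), Sox2 (-2.39) and Pou5f1 (-1.72), and 6 of 12 early germ cell genes fell (7 adjusted over the list alone), including Elf3 (-1.83) and Dppa3 (-1.29). In all, 2139 of 9372 tested genes were called, 1260 higher and 879 lower, by limma, and 1374 without the Dox replicate 1 library. By camera the lists had adjusted p = 7.1e-29 (meiotic prophase), 3.8e-13 (germline), 1.9e-25 (glycolysis), 1.6e-13 (pluripotency) and 0.00054 (early germ cell). An estimated correlation gave adjusted p = 0.00017, 0.0027, 0.00074, 0.0029 and 0.17.

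**Figure D2:**
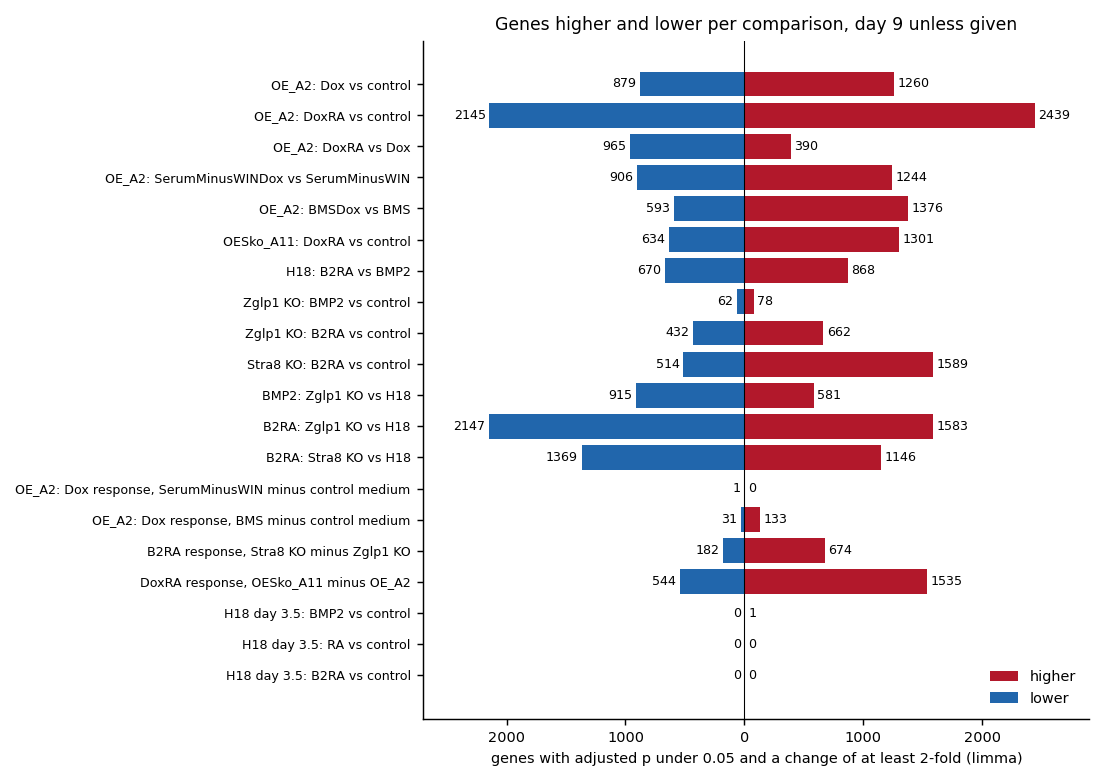
Number of genes called higher (red, to the right) and lower (blue, to the left) in each of the 20 comparisons. The bars reach 2439 higher and 2145 lower genes for DoxRA against control in OE_A2, and a single gene for BMP2 against control in H18 at day 3.5.

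DoxRA in OE_A2 asked what RA added to the transgene. Against control medium at day 9, early germ cell genes fell with DoxRA in 12 of 12 tested members (12 adjusted over the list alone), with a median of -3.64: Dppa3 (identifier 73708; chromosome 6, 122626410 to 122630272) went from 866 ± 125 to 3.51 ± 1.58 RPM (-7.63 ± 0.37, adjusted p = 9e-34), and Ifitm1 (-5.32), Tfap2c (-4.88) and Prdm14 (-3.72) fell with it. Pluripotency genes fell in 16 of 18 members (16 adjusted over the list alone), with Sox2 at 2.46 RPM against 283 ± 72.2 (-6.37 ± 0.41, adjusted p = 1.4e-25), Pou5f1 at -6.01 and Nanog at -5.80. Tdgf1, a Nodal co-receptor, had no read in either DoxRA library against 152 ± 65.7 RPM, at least 239-fold lower by a floor of 3 reads over the group, and the homeobox gene Hesx1 was at least 146-fold lower on the same floor. Meiotic prophase genes rose in 35 of 38 members and germline genes in 20 of 20 (35 and 20 adjusted over the list alone), with Ccnb3 at 230 ± 107 RPM (6.73 ± 0.47, adjusted p = 4.2e-24) and Msh4 at 85.5 RPM (6.20 ± 0.46, adjusted p = 1.3e-22). Tsc22d3, a glucocorticoid-induced leucine zipper gene, rose from 5.46 to 381 ± 60.2 RPM. Stra8 rose by 2.01 ± 0.69 to 1340 ± 257 RPM (adjusted p = 0.0093), a call lost without control replicate 2 or without DoxRA replicate 2 (adjusted p = 0.067 in both, and 0.00012 to 0.11 over the alternatives). Limma called 4584 of 9517 genes, 2439 higher and 2145 lower (2148 and 2384 with TMM factors). Camera gave the early germ cell list adjusted p = 1.2e-10, pluripotency 1.8e-16, meiotic prophase 6.3e-17, germline 2.5e-08 and glycolysis 5e-13. Under an estimated correlation adjusted p was 0.021, 0.0022, 0.0052, 0.021 and 0.021.

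Set against Dox alone at day 9, DoxRA raised genes of the RA pathway and lowered germ cell and pluripotency genes further. Cyp26a1 (identifier 13082; chromosome 19, 37697798 to 37701536), which degrades RA, rose from 0.215 ± 0.304 to 109 ± 56 RPM (6.43 ± 0.62, adjusted p = 3.2e-15), Cyp26b1 rose by 4.11 ± 0.62 (adjusted p = 6.6e-08), and the RA receptor gene Rarb by 3.56 ± 0.64 (adjusted p = 6.7e-06, but 0.055 with only the groups compared), with Dhrs3 at 2.57. Crabp2, an RA-binding protein gene, fell by 2.19. Together 5 of 10 tested RA response genes rose and 1 fell (7 and 1 adjusted over the list alone). Of 11 early germ cell genes 9 fell (10 adjusted over the list alone), led by Dppa3 (-6.34 ± 0.37, adjusted p = 1.3e-27), and 13 of 16 pluripotency genes fell (14 adjusted over the list alone), including Pou5f1 (-4.30) and Sox2 (-3.98). Of 39 meiotic prophase genes 5 rose (5 adjusted over the list alone): Ccnb3 (1.91), Msh4 (1.41), Dmc1 (1.39), Tex15 (1.17) and Stag3. Stra8 did not pass (1.16 ± 0.69, adjusted p = 0.22), except with only the groups compared (0.038). Limma called 1355 of 9121 genes, 390 higher and 965 lower, with 761 without Dox replicate 1 and 568 without Dox replicate 2. The camera test gave adjusted p = 1.4e-16 for early germ cell, 1.9e-21 for pluripotency, 0.0028 for meiotic prophase and 0.0026 for the RA response. Estimating the correlation gave adjusted p = 0.0027, 0.00022, 0.27 and 0.096. The RA response call was also lost without DoxRA replicate 1 (adjusted p = 0.96) or replicate 2 (0.89), when Cyp26a1 and other members no longer reached the level needed for testing.

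**Figure D3:**
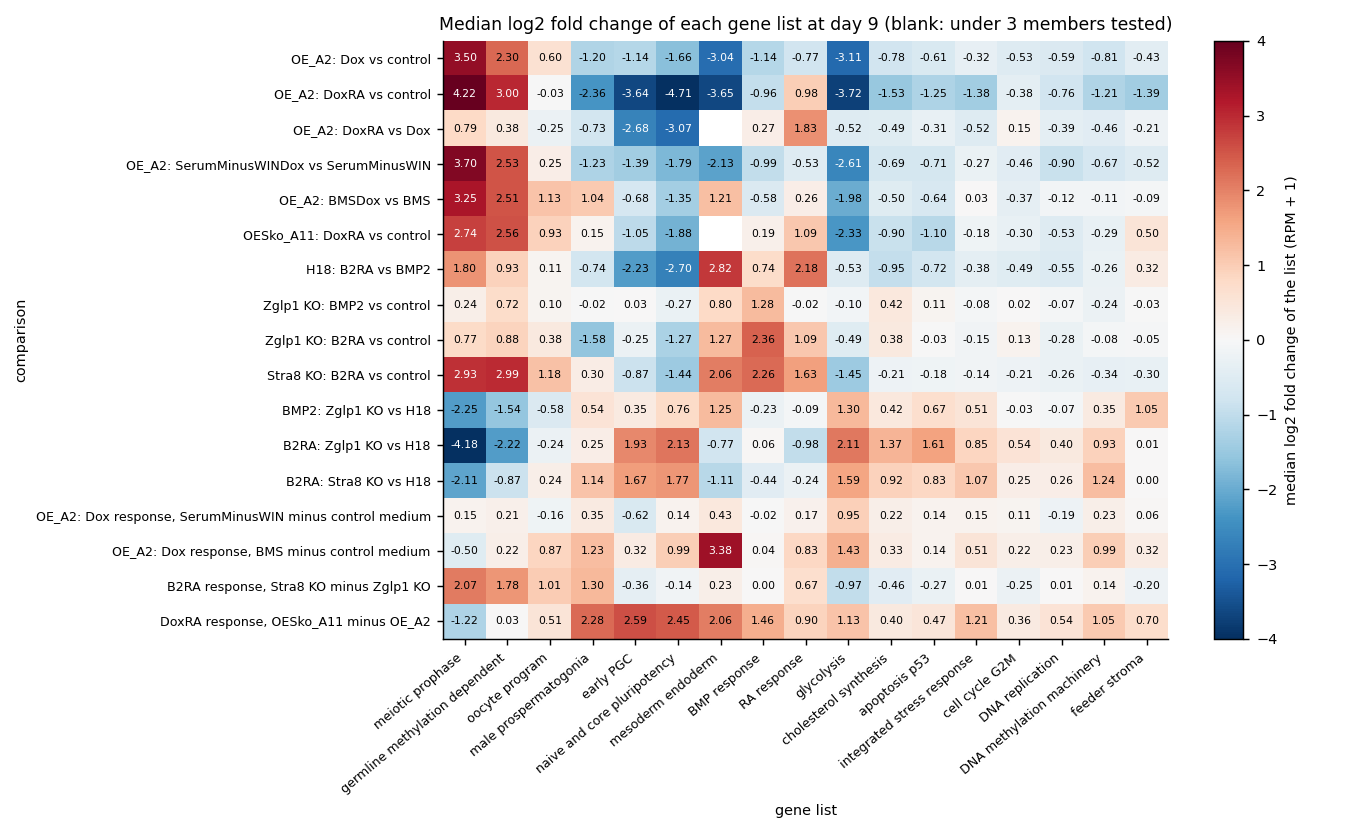
Median change (log2) of each fixed gene list in each comparison, on a colour scale from -4 to 4; blank cells had fewer than 3 tested members. The meiotic prophase list stood at 3.5 with Dox in OE_A2 and at -4.18 in the Zglp1 knockout against H18 under B2RA.

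The Dox response was also measured in serum-free medium with WIN. With SerumMinusWINDox against SerumMinusWIN at day 9 in OE_A2, meiotic prophase genes rose in 31 of 36 tested members and 1 fell (33 and 1 adjusted over the list alone), with a median of 3.70. Prdm9 rose from 2.33 to 200 ± 65.6 RPM (5.89 ± 0.59, adjusted p = 2.3e-14), Rad21l, a meiotic cohesin subunit, by 5.47 ± 0.48, and Zfp541 by 5.91 ± 0.52 (adjusted p = 9.8e-17). Germline genes rose in 17 of 20 members (17 adjusted over the list alone), including Tex101, from 14.3 ± 5.52 to 868 ± 238 RPM (5.85 ± 0.58, adjusted p = 1.7e-14). Glycolysis genes fell in 14 of 15 (15 adjusted over the list alone), with Ldha at -4.86 ± 0.77 (adjusted p = 2.6e-07), Pfkl at -4.73 ± 0.62 and the hexokinase gene Hk2 at -3.54 ± 0.47, and pluripotency genes in 16 of 19 (16 adjusted over the list alone). Stra8 did not pass (0.81 ± 0.69, adjusted p = 0.38), at 369 ± 66.1 RPM against 208 ± 22.8. Limma called 2150 of 9326 genes, 1244 higher and 906 lower, and 1130 without SerumMinusWINDox replicate 2. Tested as lists by camera, adjusted p was 6.6e-29, 2.9e-14, 8.5e-15 and 7.7e-12 for the meiotic prophase, germline, glycolysis and pluripotency lists. With an estimated correlation it was 0.00014, 0.0022, 0.011 and 0.0057. The test of the difference from the Dox response in control medium called only Athl1 (-2.60 ± 0.50, adjusted p = 0.012) among 9989 genes, with 450 at an unadjusted p under 0.05 and 0 called by edgeR. That call was lost without each of 6 of the 8 libraries, among them control replicate 1 (adjusted p = 0.71) and SerumMinusWINDox replicate 1 (0.44), and its adjusted p ran from 0.00012 to 0.96 over the alternatives. The 38 meiotic prophase genes differed by a median of 0.15 between the media (adjusted p = 0.37). Glycolysis genes differed by a median of 0.95 (adjusted p = 2e-06, and 0.39 with an estimated correlation). The mCherry level was several times higher with SerumMinusWINDox than with Dox alone, as the closing section gives. An effect of the medium on the response could be hidden by that transgene level, and the test could not separate them.

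With BMS the uninduced level of Stra8 in OE_A2 was 1.38 ± 0.354 RPM at day 9, against 332 ± 63 in control medium, and Dox raised it to 33.7 ± 6.16 RPM (3.86 ± 0.69, adjusted p = 6.5e-06). Meiotic prophase genes rose with Dox in BMS in 28 of 34 tested members and 1 fell (28 and 1 adjusted over the list alone), with a median of 3.25, and germline genes rose in 19 of 20 (19 adjusted over the list alone). Zfp541 rose by 5.58 ± 0.52 (adjusted p = 3.5e-15), Meioc, which sustains the meiotic programme, from 6.30 to 200 ± 118 RPM (4.98 ± 0.65), and Majin, which tethers telomeres in meiosis, by 4.91 ± 0.57. Of 11 oocyte genes 6 rose and 1 fell (6 and 1 adjusted over the list alone): Nobox stood at 38.5 ± 3.61 RPM against no read in either BMS library, at least 73.7-fold higher by a floor of 3 reads over the group, and Lhx8 (4.54), Figla (4.35) and Sohlh1 (3.05) rose with it. Glycolysis genes fell in 15 of 16 (15 adjusted over the list alone), and pluripotency genes in 9 of 18 (10 adjusted over the list alone), with Tdgf1 at -3.36 ± 0.64 (adjusted p = 2.1e-05). Zglp1 rose by 1.72 ± 0.50 (adjusted p = 0.0048), a call lost without BMS replicate 1 (0.32, the top of a range from 0.00062 over the alternatives). Limma called 1969 of 9279 genes, 1376 higher and 593 lower, where scaling by TMM factors gave 885 and 938, and leaving out BMS replicate 1 or BMSDox replicate 2 gave 1198 and 1109. In the camera test adjusted p was 2.6e-19, 3.3e-14, 3.3e-14 and 4.2e-10 for meiotic prophase, germline, glycolysis and pluripotency. An estimated correlation gave adjusted p = 0.0017, 0.0017, 0.0095 and 0.0095. The oocyte list passed both ways (camera adjusted p = 0.00012 and 0.0017). That call was lost without BMSDox replicate 1 or replicate 2, when Nobox, with no read in BMS, no longer reached the level needed for testing.

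The Dox response with BMS differed from that in control medium in 164 of 10015 genes. Limma called 133 higher and 31 lower, against 73 and 53 with TMM factors and 10 and 11 with edgeR. Mesoderm genes stood out: 2 of 4 tested members were higher (3 adjusted over the list alone), Sp5, a Wnt target, by 5.63 ± 0.89 (adjusted p = 6.4e-05) and Hand1 by 4.38 ± 1.04 (adjusted p = 0.011). The Nodal antagonists Lefty2 (4.67 ± 0.94, adjusted p = 0.0022) and Lefty1 (4.03 ± 0.87, adjusted p = 0.0048) and the piRNA factor Pnldc1 (1.84) made up 3 of 11 members of the list for male prospermatogonia (4 adjusted over the list alone). Both Lefty genes were already low with BMS before induction: Lefty1 stood at 13.2 ± 4.83 RPM with BMS and 31.5 ± 13.1 with BMSDox, against 302 ± 170 in control medium and 38.1 ± 9.56 with Dox. Lefty2 stood at 6.4 ± 4.28 and 5.67 ± 2.69 RPM, against 131 ± 47.5 and 3.75 ± 0.162. Glycolysis genes were higher in 3 of 16 members (11 adjusted over the list alone), with Ldha at 3.94 ± 1.09 (adjusted p = 0.035, and 0.015 to 0.31 over the alternatives). Of 38 meiotic prophase genes Msh4 was lower (-2.97 ± 0.65, adjusted p = 0.0048, and 7.6e-05 to 0.093 over the alternatives), with 2 higher and 1 lower adjusted over the list alone. Stra8 (3.01 ± 0.98, adjusted p = 0.088) and Zglp1 (1.9 ± 0.71, adjusted p = 0.15) did not pass. Stra8 passed with a term for replicate number (0.012) and with only the groups compared (0.0021), and Zglp1 passed without BMS replicate 2 (2.73). By camera the adjusted p was 0.002 for mesoderm, 0.00062 for male prospermatogonia and for meiotic prophase, and 2.2e-06 for glycolysis. Under an estimated correlation adjusted p was 0.026, 0.026, 0.34 and 0.14. The count fell to 8 without control replicate 1, 49 without Dox replicate 1, 79 without Dox replicate 2, 67 without BMS replicate 1 and 59 without BMSDox replicate 1. Over the alternatives the adjusted p of Lefty1 reached 0.15, that of Lefty2 0.093 and that of Hand1 0.26.

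In H18 the question was which genes answered BMP2 or RA first, at the earliest day sampled, day 3.5. BMP2 raised Id1 (identifier 15901; chromosome 2, 152736251 to 152737410), an early target of BMP signalling, from 6.63 ± 0.49 to 50.3 ± 2.78 RPM (2.75 ± 0.57, adjusted p = 0.047), which was the only gene called among 8390 by limma (163 at an unadjusted p under 0.05) and 1 gene by edgeR. No gene passed without any 1 of the 4 libraries. Without control replicate 1 or 2 the change of Id1 was 2.82 and 2.69 (adjusted p = 0.33 and 1), and without either BMP2 library Id1 no longer reached the level needed for testing. With TMM factors the count was also 0 (2.71, adjusted p = 0.073), and the adjusted p of Id1 ran from 0.0037 to 1.0 over the alternatives. Of 9 BMP response genes that was the 1 that rose (1 adjusted over the list alone), and the list had a median of 0.51 (camera adjusted p = 0.00093, and 0.18 with an estimated correlation). It did not pass without control replicate 1 (0.081), nor without BMP2 replicate 1 (0.77) or BMP2 replicate 2 (0.27), when Id1 dropped out of the list. For RA limma called 0 of 8377 genes, with 283 at an unadjusted p under 0.05 and 0 by edgeR, and for B2RA 0 of 8393, with 510 and 0. Without RA replicate 1 the RA count was 153, and without control replicate 1 the B2RA count was 23. The BMP response list with B2RA had adjusted p = 0.044 (0.97 with an estimated correlation). Zglp1 was below the level for testing, at 0.942 ± 1.33 RPM in control medium, 5.96 ± 0.876 with BMP2, 1.41 with RA and 6.98 ± 1.57 with B2RA.

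By day 9 in H18, the addition of RA to BMP2 was compared with BMP2 alone. Pluripotency genes fell in 16 of 18 tested members (16 adjusted over the list alone), with Pou5f1 (identifier 18999; chromosome 17, 35506018 to 35510772) at 8.61 ± 2.51 RPM against 220 ± 106 (-4.46 ± 0.46, adjusted p = 4.1e-13) and Nanog at -3.56. Early germ cell genes fell in 10 of 12 (10 adjusted over the list alone), including Dppa3 (-3.54) and Prdm14 (-3.49). Meiotic prophase genes rose in 29 of 39 and 1 fell (32 and 1 adjusted over the list alone), with Ccnb3 at 3.91, Rad51ap2 at 3.30, Prdm9 at 2.89 and Sycp2, of the synaptonemal complex, at 2.81. RA response genes rose in 5 of 10 (5 adjusted over the list alone): Cyp26a1 stood at 269 ± 169 RPM against no read in either BMP2 library, at least 606-fold higher by a floor of 3 reads over the group, and Cyp26b1 (4.36 ± 0.62), Dhrs3 (3.90) and Rarb (3.5) rose. Genes of mesoderm rose in 4 of 5 and Lhx1 fell (the same numbers adjusted over the list alone), with Gata4 at 4.37 ± 0.64, Tbx20 at 3.66 and Pdgfra at 2.82. Of 13 feeder and stroma genes 3 rose, including Col3a1 (2.67) and Col1a1 (2.44), and that list did not pass (adjusted p = 0.24; 0.0014 without BMP2 replicate 2 and 0.024 without B2RA replicate 2). Stra8 rose by 2.19 ± 0.69 to 731 ± 104 RPM (adjusted p = 0.014), a call lost without BMP2 replicate 1 (0.056), BMP2 replicate 2 (0.12) or B2RA replicate 2 (0.09), and Zglp1 did not pass (-0.13 ± 0.50, adjusted p = 0.88). Limma called 1538 of 9594 genes, 868 higher and 670 lower, where edgeR gave 617 and 717, and 304 without BMP2 replicate 2. The camera test gave adjusted p = 4.2e-29, 9.1e-14, 2.7e-14, 5.5e-06 and 0.0099 for pluripotency, early germ cell, meiotic prophase, RA response and mesoderm. Estimating the correlation gave adjusted p = 9.2e-06, 0.0072, 0.0072, 0.0054 and 0.062. The RA response call was lost without B2RA replicate 1 (0.73) or replicate 2 (0.80), when members such as Cyp26a1 dropped out of testing.

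**Figure D4:**
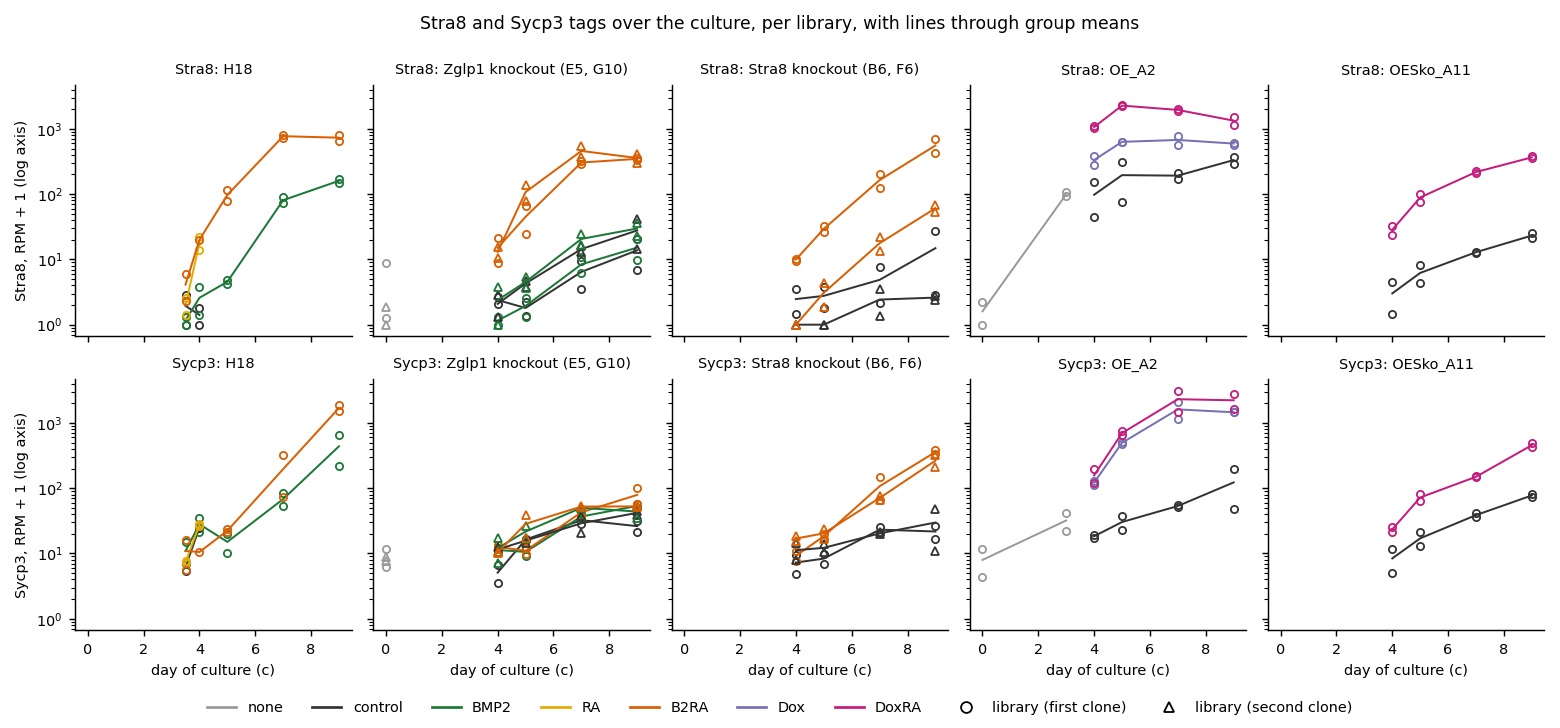
RPM + 1 (log axis) of Stra8 (top) and Sycp3 (bottom) by day of culture in H18, the Zglp1 knockout clones (circles E5, triangles G10), the Stra8 knockout clones (circles B6, triangles F6), OE_A2 and OESko_A11; points are libraries and lines join group means. Under B2RA at day 9, Sycp3 stood at 1700 RPM in H18 and at 78.1 and 51.7 RPM in the Zglp1 knockout clones.

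The Zglp1 knockout clones asked which parts of the BMP and RA responses needed the gene. BMP2 against control at day 9 raised BMP targets in 6 of 11 tested members (7 adjusted over the list alone), with a median of 1.28: Id1 rose from 10.9 ± 2.97 to 140 ± 41 RPM (3.56 ± 0.41, adjusted p = 9.5e-11, n = 4), Gata2 by 1.44, Bambi by 1.43 and Id2 by 1.40. Phlda2, an imprinted growth regulator, rose by 3.14 ± 0.44 (adjusted p = 1.6e-07). Robo3 fell by 4.56 ± 0.55 (adjusted p = 6.8e-10), with Nnat at -3.87 ± 0.48, Sox11 at -3.66 ± 0.51 and Tubb3 at -3.05. Tags of Zglp1 itself rose by 2.31 ± 0.35 (adjusted p = 1.6e-06), from 2.64 ± 1.07 to 19.2 ± 12 RPM, and Stra8 did not pass (0.25 ± 0.49, adjusted p = 0.91). No member of the meiotic prophase list passed among 19 by limma (2 adjusted over the list alone), and Ddx4 (1.38) and Asz1 (1.17) were the 2 of 14 germline genes that rose (3 adjusted over the list alone). Limma called 140 of 9565 genes, 78 higher and 62 lower, with 77 without E5 control replicate 2, 74 without G10 control replicate 2 and 79 without G10 BMP2 replicate 2. Tested as lists by camera, adjusted p was 2.4e-14 for the BMP response and 2.2e-07 for germline, with 1e-05 and 0.045 under an estimated correlation. The meiotic list had a median of 0.24 and adjusted p = 0.011 (0.32 with an estimated correlation), and lost that call without E5 control replicate 1 (0.057), E5 BMP2 replicate 2 (0.054) or G10 control replicate 1 (0.2).

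B2RA against control in the Zglp1 knockout clones raised 11 of 13 BMP response genes (11 adjusted over the list alone), with Id1 at 434 ± 61.7 RPM (5.22 ± 0.41, adjusted p = 3.6e-19), Phlda2 at 485 ± 67.1 (5.32 ± 0.44, adjusted p = 2.1e-17) and the homeobox gene Msx1 at 4.77 ± 0.41. Hamp, the hepcidin gene, stood at 32.8 ± 5.61 RPM against no read in the control libraries, at least 104-fold higher by a floor of 3 reads over the group. Stra8 rose from 19.8 ± 14.7 to 351 ± 48.2 RPM (4.36 ± 0.49, adjusted p = 9.4e-12), as did Zglp1 tags (2.78 ± 0.35, adjusted p = 4.6e-10). Of 22 meiotic prophase genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with Rec8, a meiotic cohesin, at 2.58, Tex12 at 2.17 and Terb2 at 1.70, and Sgol2 at -1.48. Germline genes rose in 6 of 16 (6 adjusted over the list alone), including Taf7l (2.88) and Tex101 (2.68). Pluripotency genes fell in 15 of 20 and Tbx3 rose (15 and 1 adjusted over the list alone), with Tdgf1 at -4.94 ± 0.46 (adjusted p = 1.6e-15), Nanog at -1.53 and Sox2 at -1.46, and Otx2 was at least 125-fold lower on the same floor. RA response genes rose in 5 of 9 and 1 fell (5 and 1 adjusted over the list alone), among them Rarb (2.71). Limma called 1094 of 9980 genes, 662 higher and 432 lower (486 and 548 with TMM factors). In the camera test adjusted p was 8.6e-15, 8.1e-17, 0.00026, 2.8e-06 and 0.018 for BMP response, pluripotency, meiotic prophase, germline and RA response. With an estimated correlation it was 5e-06, 0.0004, 0.16, 0.063 and 0.17. The RA response call was lost without E5 B2RA replicate 1 (0.073) or G10 control replicate 1 (0.081).

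Set against H18 under BMP2 at day 9, the Zglp1 knockout clones held less mRNA of meiotic genes. H18 had no control library at day 9, so a difference in response could not be told apart from one present without BMP2. The same limit holds for both knockouts against H18 under B2RA. Of 27 tested meiotic prophase genes 21 were lower (21 adjusted over the list alone), with a median of -2.25, and of 18 germline genes 12 were lower (12 adjusted over the list alone). Sycp1, of the synaptonemal complex, stood at 0.683 ± 0.861 RPM (n = 4) against 138 ± 131 in H18 (-6.06 ± 0.57, adjusted p = 2.7e-15), Taf7l at -5.04 ± 0.51, Sycp2 at -4.95 ± 0.50 and Tex101 at -4.94 ± 0.50, and Stra8 fell to 21.5 ± 11.1 against 159 ± 17.9 RPM (-2.98 ± 0.60, adjusted p = 7.1e-05). Glycolysis genes were higher in 14 of 16 (14 adjusted over the list alone), with Pfkl at 3.25 ± 0.54, pluripotency genes in 5 of 19 (5 adjusted over the list alone; camera adjusted p = 1.9e-05, and 0.1 with an estimated correlation), and feeder and stroma genes in 6 of 14 (7 adjusted over the list alone; median 1.05, adjusted p = 0.0018, and 0.17 with an estimated correlation). The imprinted noncoding gene Meg3 was higher by 4.15 ± 0.58 (adjusted p = 2.2e-08). Limma called 1496 of 9575 genes, 581 higher and 915 lower (741 and 691 with TMM factors), and 608 without H18 BMP2 replicate 1. By camera the adjusted p was 3.9e-19, 1.1e-10 and 1.1e-11 for meiotic prophase, germline and glycolysis. An estimated correlation gave adjusted p = 0.00054, 0.015 and 0.035. The 2 H18 libraries differed, with Sycp1 at 231 and 44.9 RPM: without replicate 1 the meiotic prophase median was -1.31 (adjusted p = 2e-06) and without replicate 2 it was -2.35 (1.6e-14). The feeder and stroma call was lost without H18 BMP2 replicate 1 (0.088). The clones and H18 also differed along chromosome X, whose 321 tested genes had a median of -0.60 against -0.10 for the rest. Of the called genes 107 lay on X, 1243 on other chromosomes and 146 had no single position in the annotation.

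Under B2RA at day 9 the Zglp1 knockout clones differed from H18 in 3730 of 10246 genes, 1583 higher and 2147 lower. Meiotic prophase genes were lower in 34 of 39 tested members (34 adjusted over the list alone), with a median of -4.18: Rad21l stood at 0.0842 ± 0.168 RPM against 191 ± 7.84 (-7.48 ± 0.41, adjusted p = 9.2e-31), Rad51ap2 at 0.168 against 206 ± 98.6 (-7.42 ± 0.41, adjusted p = 9.2e-31) and Ccnb3 at 0.311 against 101 ± 27.3 (-6.31 ± 0.41). Germline genes were lower in 17 of 19 (17 adjusted over the list alone), and Figla by -5.88. Early germ cell genes were higher in 14 of 14 (14 adjusted over the list alone), including Ifitm1 (3.30), Dppa3 (3.08) and Tfap2c (2.67), and pluripotency genes in 15 of 18 (15 adjusted over the list alone), including Nanog at 116 ± 35.6 against 6.32 ± 0.189 RPM (3.94 ± 0.41, adjusted p = 3.8e-14) and Pou5f1 (3.71). Stra8 stood at 351 against 731 RPM and did not pass (-1.06 ± 0.60, adjusted p = 0.13). It did with pseudocount 5 (0.021), with a term for replicate number (0.035) and with only the groups compared (0.0026). Sycp3 (identifier 20962; chromosome 10, 88459569 to 88473236) stood at 78.1 ± 31.5 and 51.7 ± 2.61 RPM in the clones against 1700 ± 258. RA response genes were lower in 4 of 11 (4 adjusted over the list alone), among them Cyp26a1 (-3.61) and Cyp26b1 (-3.5), and that list did not pass (adjusted p = 0.15). The camera test gave adjusted p = 1.5e-24, 1.9e-09, 1e-08 and 1.2e-11 for meiotic prophase, germline, early germ cell and pluripotency. Under an estimated correlation adjusted p was 0.0007, 0.017, 0.036 and 0.0063. The 364 tested genes of chromosome X had a median of -0.73 against -0.06 elsewhere, with 184 called genes on X, 3168 on other chromosomes and 378 without a single position.

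The Stra8 knockout clones asked which parts needed Stra8. B2RA against control at day 9 raised 29 of 34 tested meiotic prophase genes and 1 fell (29 and 1 adjusted over the list alone), with a median of 2.93, and 18 of 20 germline genes (18 adjusted over the list alone). Tex101 rose from 2.51 ± 1.54 to 380 ± 130 RPM (6.85 ± 0.41, adjusted p = 8.9e-28), Sycp2 from 0.571 ± 0.506 to 89.0 ± 8.93 (5.89 ± 0.41, adjusted p = 9e-24), Taf7l by 6.62 ± 0.41, Zfp541 by 5.70 and Rec8 (identifier 56739; chromosome 14, 55618037 to 55625395) by 4.14. Of 7 oocyte genes 4 rose (4 adjusted over the list alone): Figla (4.52), Sohlh1 (3.99), Ybx2 (2.06) and Sohlh2 (1.18). BMP response genes rose in 12 of 14 (12 adjusted over the list alone), with Id1 at 5.63, and RA response genes in 9 of 14 (9 adjusted over the list alone), with Cyp26a1 at 4.10. Zglp1 rose from 4.76 ± 2.99 to 50.2 ± 23 RPM (3.18 ± 0.35, adjusted p = 6.1e-13), and remaining tags of Stra8 from 7.74 ± 12.1 to 308 ± 306 (5.24 ± 0.49, adjusted p = 1e-15). Glycolysis genes fell in 12 of 16 and pluripotency genes in 14 of 19 (12 and 14 adjusted over the list alone). Limma called 2103 of 10111 genes, 1589 higher and 514 lower (1109 and 796 with TMM factors). Tested as lists by camera, adjusted p was 1.2e-21, 3.8e-23, 1.4e-06, 0.0048, 3.3e-12 and 9.6e-15 for meiotic prophase, germline, BMP response, RA response, glycolysis and pluripotency. Estimating the correlation gave adjusted p = 0.00076, 5.8e-05, 0.003, 0.092, 0.02 and 0.0013.

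Compared with H18 under B2RA at day 9, the Stra8 knockout clones were lower in 32 of 39 meiotic prophase genes and higher in Rec8 (32 and 1 adjusted over the list alone), with a median of -2.11. Rad51ap2 stood at 4.07 ± 3.54 against 206 ± 98.6 RPM (-5.68 ± 0.41), Rad21l at 8.86 ± 3.95 against 191 ± 7.84 (-4.38 ± 0.41, adjusted p = 1.9e-15), Prdm9 at -3.81 and Terb1, of the telomere complex, at -3.36, whereas Rec8 was higher by 1.43. Of 20 germline genes 8 were lower, among them Dazl (-1.66), and Tdrd1 was higher by 1.25 (8 and 1 adjusted over the list alone). Early germ cell genes were higher in 13 of 14 and pluripotency genes in 15 of 17 (13 and 15 adjusted over the list alone), with Pou5f1 at 118 ± 26.9 against 8.61 ± 2.51 RPM (3.62 ± 0.40, adjusted p = 2.9e-12) and Nanog at 3.24. Tags of Stra8 were lower by -2.01 ± 0.60 (adjusted p = 0.0045), a call lost in clone B6 alone (adjusted p = 0.65) and without H18 B2RA replicate 2 (0.058), with 7.3e-06 to 0.65 over the alternatives. Limma called 2515 of 10131 genes, 1146 higher and 1369 lower (1250 and 1236 with TMM factors). In the camera test adjusted p was 1.6e-15, 0.02, 1.7e-09 and 8.5e-16 for meiotic prophase, germline, early germ cell and pluripotency. With an estimated correlation it was 0.009, 0.33, 0.05 and 0.0022. The 363 tested genes of chromosome X had a median of -0.46 against -0.01 elsewhere. Of the called genes 113 lay on X, 2148 on other chromosomes and 254 had no single position. The value pools clones that stood apart on X over all days, at 0.448 in Sko_F6 and -0.228 in Sko_B6 against the other lines. H18 stood at 0.399 on that scale.

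The B2RA response itself differed between the knockouts. The response of the Stra8 knockout minus that of the Zglp1 knockout was higher in 24 of 34 tested meiotic prophase genes (25 adjusted over the list alone), with a median of 2.07, in 17 of 20 germline genes (18 adjusted over the list alone), and in 3 of 7 oocyte genes (4 adjusted over the list alone), Figla (4.13), Sohlh1 (3.45) and Ybx2. Sycp2 differed by 4.24 ± 0.58 (adjusted p = 4.4e-08), Meioc by 4.18 ± 0.65 (adjusted p = 1.1e-06), Tex101 by 4.16 ± 0.58 (adjusted p = 5.8e-08) and Zfp541 by 4.75 ± 0.52 (adjusted p = 2.2e-11), the last not called by edgeR (adjusted p = 1, against a lowest of 1.2e-16 over the alternatives). Stra8 (0.88 ± 0.69, adjusted p = 0.46) and Zglp1 (0.40 ± 0.50, adjusted p = 0.67) did not pass, and the BMP response list did not pass either (adjusted p = 0.21). Glycolysis genes were lower in 4 of 16 (7 adjusted over the list alone). Limma called 856 of 10648 genes, 674 higher and 182 lower (561 and 256 with TMM factors), and edgeR 273. The count was 1482 without E5 B2RA replicate 1 and 476 without E5 B2RA replicate 2. By camera the adjusted p was 2e-21, 3.1e-21, 0.00048 and 6e-08 for meiotic prophase, germline, oocyte and glycolysis. An estimated correlation gave adjusted p = 0.00074, 0.00016, 0.0047 and 0.078.

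In OESko_A11, which asked what the transgene did without Stra8, DoxRA against control at day 9 raised 30 of 35 tested meiotic prophase genes and 18 of 20 germline genes (30 and 19 adjusted over the list alone). Tex101 rose from 13.1 ± 2.2 to 861 ± 131 RPM (5.94 ± 0.58, adjusted p = 9.1e-15), Zfp541 by 5.96 ± 0.52 (adjusted p = 8.1e-17) and Taf7l by 5.49 ± 0.58, and Ccnb3 stood at 42.7 ± 11.7 RPM against no read in either control library, at least 58.9-fold higher by a floor of 3 reads over the group. Remaining Stra8 tags rose from 22.2 ± 2.69 to 365 ± 18.1 RPM (3.98 ± 0.69, adjusted p = 3.9e-06), and Zglp1 tags did not pass (1.07 ± 0.50, adjusted p = 0.093), except with only the groups compared (0.045). Glycolysis genes fell in 14 of 16 and pluripotency genes in 14 of 18 (14 and 14 adjusted over the list alone), with Pfkl at 0.96 against 103 ± 16.2 RPM (-5.72 ± 0.62, adjusted p = 2e-12), Ldha at -4.36 ± 0.77 (adjusted p = 4.8e-06) and the triose phosphate isomerase gene Tpi1 at -4.15 ± 0.51. RA response genes rose in 6 of 12 (6 adjusted over the list alone), with Cyp26a1 at 4.21 and Dhrs3 at 3.56 (camera adjusted p = 0.01, and 0.088 with an estimated correlation), a call lost without DoxRA replicate 1 (0.28) or replicate 2 (0.78). Limma called 1935 of 9663 genes, 1301 higher and 634 lower (893 and 903 with TMM factors), with 946 without DoxRA replicate 1 and 1230 without control replicate 2. The camera test gave adjusted p = 1.8e-21, 1.1e-16, 2.5e-21 and 3.6e-16 for meiotic prophase, germline, glycolysis and pluripotency. Under an estimated correlation adjusted p was 0.00067, 0.00067, 0.00088 and 0.00088.

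The DoxRA response of OESko_A11 differed from that of OE_A2 in 2079 of 10372 genes, 1535 higher and 544 lower. Pluripotency genes differed in 12 of 19 tested members, all 12 higher (14 adjusted over the list alone), with Sox2 at 4.59 and Pou5f1 at 4.03, and early germ cell genes in 9 of 14 (9 adjusted over the list alone), with Dppa3 at 6.35 ± 0.52 (adjusted p = 1.8e-17). The Nodal antagonist Lefty1 differed by 6.69 ± 0.87 (adjusted p = 5e-09), and the BMP targets Id1 by 4.22 and Id3 by 3.55. Of 38 meiotic prophase genes 12 were lower, including Meiob (-2.73), Msh4 (-2.65) and Dmc1 (-2.29), and Rec8 was higher by 2.45 (15 and 1 adjusted over the list alone). Cyp26b1 was lower (-4.25 ± 0.88, adjusted p = 0.00011), and of 20 germline genes 1 was lower (1 adjusted over the list alone; list median 0.03, adjusted p = 0.24). Stra8 (1.98 ± 0.98, adjusted p = 0.14) and Zglp1 (0.16 ± 0.71, adjusted p = 0.9) did not pass. Stra8 did with pseudocount 5 (0.038), with a term for replicate number (0.035) and with only the groups compared (0.0023). Tested as lists by camera, adjusted p was 8.7e-11, 3.3e-08 and 2.2e-06 for pluripotency, early germ cell and meiotic prophase. Estimating the correlation gave adjusted p = 0.022, 0.079 and 0.17.

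The order of events was followed through days 4, 5, 7 and 9. Because the members tested changed from day to day (21 meiotic prophase genes with Dox at day 4 and 38 at day 9), medians here are over the same members at every day and in every line, a choice made after the data had been seen. The median change of 39 meiotic prophase genes at days 4, 5, 7 and 9 was 1.16, 2.37, 3.75 and 3.48 with Dox in OE_A2, 0.59, 1.28, 3.52 and 3.57 with SerumMinusWINDox, 0.59, 1.3, 3.05 and 2.78 with BMSDox, and 0.37, 0.84, 1.45 and 2.74 with DoxRA in OESko_A11. With B2RA it was 0.19, 0.23, 1.16 and 2.58 in the Stra8 knockout clones and 0.02, 0.18, 0.63 and 0.73 in the Zglp1 knockout clones. The 15 BMP response genes had medians of 0.88, 1.19, 2.03 and 2.06 in the Zglp1 knockout with B2RA, and 16 RA response genes had 1.24, 1.93, 1.39 and 1.37 with DoxRA against Dox. The 16 glycolysis genes stood at 0.25, -0.42, -1.91 and -3.04 with Dox in OE_A2. The meiotic list passed camera at day 4 with Dox (adjusted p = 1e-09, and 0.029 with an estimated correlation), and at day 4 with B2RA in the Zglp1 knockout it did not (adjusted p = 0.067). Genes called at days 4, 5 and 7 numbered 840, 1065 and 2313 with Dox and 43, 90 and 480 with B2RA in the Zglp1 knockout. At those days the Dox and control libraries of OE_A2 had been made by different extraction protocols, so protocol and Dox could not be told apart there, whereas the day 9 libraries shared one protocol. The same limit holds for the SerumMinusWIN difference at day 5, where 30 tested meiotic prophase genes had a median of -1.3 (adjusted p = 2.1e-12, and 0.018 with an estimated correlation) and 20 germline genes one of -0.88 (2.4e-09 and 0.023).

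Responses measured against separate control libraries were set side by side across genes, which are not independent replicates, in 7 pairs at day 9. The Dox response of OE_A2 correlated at 0.875 with that in SerumMinusWIN and at 0.738 with that in BMS; 879 genes rose and 500 fell in both of the first pair, against 157 and 79.1 for independent lists, and 661 rose and 296 fell in both of the second, against 163 and 47.1. The B2RA response of the Stra8 knockout correlated at 0.819 with the DoxRA response of OESko_A11, with 799 genes higher in both against 177, and at 0.669 with the B2RA response of the Zglp1 knockout, with 401 against 75.5. The Dox response and the B2RA response of the Zglp1 knockout correlated at 0.294, with 105 genes higher in both against 49.9, 110 lower in both against 26.4, and 58 in opposite directions.

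The embryonic libraries had no replicates and were not tested. From E9.5 primordial germ cells to E15.5 oocytes, Sycp3 went from 3.59 to 2690 RPM, Stra8 from 0.239 to 508, Figla (identifier 26910; chromosome 6, 86016171 to 86020996) from 0.239 to 197, and Dppa3 from 2490 to 39.7. The meiotic prophase list stood 6.57 higher at E15.5, above all 10000 random lists matched on expression (100th percentile), the germline list 5.37 higher (100th), and the glycolysis list at -4.08 and the pluripotency list at -4.66 (both at percentile 0). Across 10082 genes, E9.5 and E15.5 correlated at 0.539. At day 9 the mean correlation with E15.5 was 0.616 in control OE_A2, 0.873 with Dox and 0.883 with DoxRA, 0.744 in H18 with BMP2 (0.666 and 0.823) and 0.881 with B2RA, 0.536 and 0.577 in the Zglp1 knockout clones with B2RA, 0.704 and 0.695 in the Stra8 knockout clones with B2RA, and 0.776 in OESko_A11 with DoxRA.

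**Figure D5:**
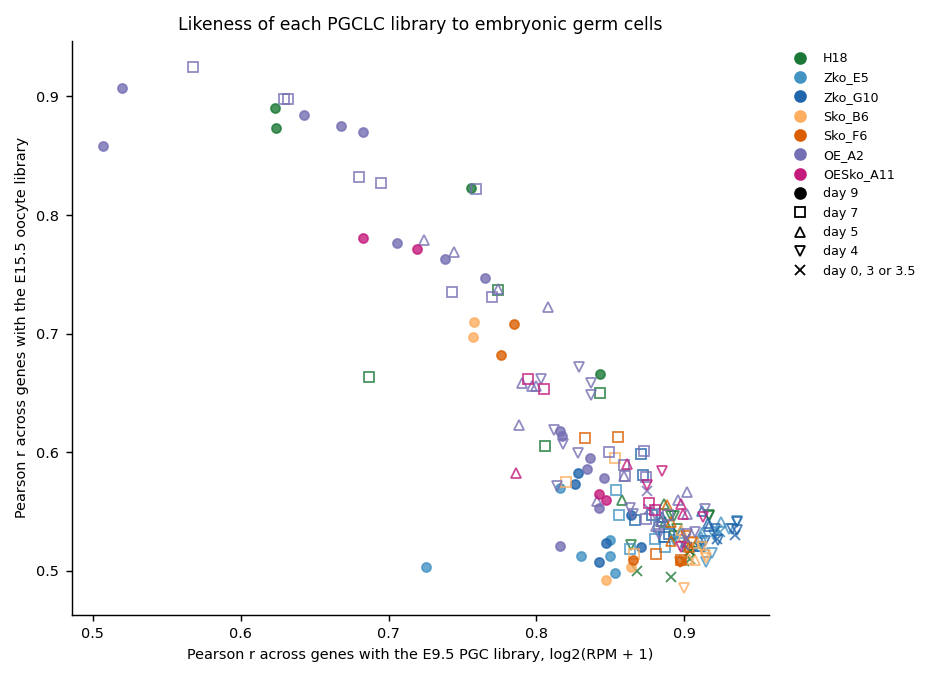
Pearson correlation across genes of each PGCLC library with E9.5 primordial germ cells (x) and with E15.5 oocytes (y), with colours for lines, shapes for days of culture and filled markers for day 9. OE_A2 with DoxRA at day 9 averaged 0.514 on the x axis and 0.883 on the y axis.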

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

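The tests of more transgene mRNA with BMS, of less transgene mRNA in OESko_A11 and of uninduced OESko_A11 against the Stra8 knockout, and the overlaps of calls without a library, were chosen only after related values had been seen, and the other tests before. Tests of the difference between responses singled out 4 results at day 9. These were the Dox response with SerumMinusWIN minus that in control medium (1 gene), the Dox response with BMS minus that in control medium (164 genes), the B2RA response of the Stra8 knockout minus that of the Zglp1 knockout (856 genes), and the DoxRA response of OESko_A11 minus that of OE_A2 (2079 genes). Signal outside the main measurement appeared in the transgene row: mCherry tags stood at 284 RPM in uninduced OE_A2 and 176 RPM in uninduced OESko_A11 at day 9, and at 217 RPM in the E14.5 and 231 RPM in the E15.5 oocyte library, against 0 in the E9.5 library. The labels give the later embryos a Ddx4-RFP reporter, and whether its mRNA was read in the mCherry row was not tested.

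The Dox response with BMS could differ because more transgene mRNA was made, 10300 RPM against 1290 with Dox alone. SerumMinusWINDox also raised it, to 6290 RPM, and over 128 genes called higher with BMS the SerumMinusWIN difference had a median of 0.41 against 1.75, or 23.3 percent (95% bounds 17.4 to 30.6 over resampled genes). That decides nothing, since the genes were chosen for the BMS difference and both differences subtract the same Dox and control libraries, and nor does the median of -0.78, of a difference of 1.8, for uninduced BMS against control, whose libraries enter that difference too. The shallow BMSDox replicate 2 library is an unlikely sole cause, since 138 genes were called without it, 99 of them among the 164. The count did hang on other single libraries, falling furthest without control replicate 1, and edgeR called only 10 genes higher and 11 lower. A biological effect of BMS on the response remained possible and was not separable from dose.

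Stra8 tags stood at 332 RPM in uninduced OE_A2 and at 13.9 and 1.6 RPM in the uninduced Stra8 knockout clones. In the uninduced Zglp1 knockout clones, which carry no transgene, they stood at 19.8 ± 14.7 RPM (n = 4). In uninduced OE_A2 without serum and with WIN, Stra8 tags stood at 208 ± 22.8 RPM. Expression of the transgene without Dox could contribute: the 1244 genes that rose with Dox in SerumMinusWIN were higher in uninduced OE_A2 than in the Stra8 knockout by a median of 0.42, at percentile 100 of 10000 random lists (0.2 to 0.29). Signalling that BMS blocks could contribute as well. The RA response list was lower with BMS in uninduced cells (camera adjusted p = 0.008, and 0.066 with an estimated correlation). Crabp2, which fell with BMS there, also fell when RA was added to Dox, so its fall does not show less RA signalling. Both predictions were met as written, that of the RA response list only with the preset correlation, and the tests do not rank them. Because Crabp2 counts towards the list, meeting that prediction does not by itself show less RA signalling. In uninduced OE_A2 at day 9 mCherry tags stood at 69.7 ± 37.1 RPM with BMS against 284 ± 172 in control medium. A fall of Stra8 with BMS therefore cannot separate blocked signalling from less transgene mRNA. Uninduced OE_A2 also differs from the Stra8 knockout clones in Stra8 itself. Uninduced OESko_A11, which lacks Stra8 too, stood above those clones by a median of 0.27 (0.13 to 0.19 for its own random lists). That was smaller than in OE_A2.

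Less transgene mRNA as the cause of the smaller response of OESko_A11 to DoxRA stays open: at day 9 the mCherry level was 1.53 times that of OE_A2, but single libraries overlapped (ratios of 0.829 to 3.41). It was 0.333, 0.25 and 0.389 times at days 4, 5 and 7, when the OE_A2 libraries were wholly or partly of another extraction protocol, so clone and protocol cannot be told apart there. The shallow OE_A2 DoxRA replicate 2 library is not a likely cause, since 1765 genes were called without it, 1376 of them among the 2079. Uninduced OESko_A11 did not hold more of the response than uninduced OE_A2: over 1135 genes its median difference from OE_A2 was -0.12, against a shortfall of 0.78. Both held mCherry tags without Dox, at 176 RPM in OESko_A11 and 284 RPM in OE_A2. The comparison therefore does not show that uninduced OESko_A11 held none of the response. Loss of Stra8 could explain the difference, but 1 clone of each kind cannot separate it from clone or from transgene level.

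For the knockouts, libraries were also regrouped by exchanging labels, with no clone term. The real split was the 1 of 35 with as many genes for BMP2 in the Zglp1 knockout (135 against at most 63), 1 of 35 for B2RA in the Zglp1 knockout (1088 against at most 538) and 1 of 35 for B2RA in the Stra8 knockout (2099 against at most 698). For the difference of B2RA responses it was 1 of 3 splits of the clones (856 against at most 36), too few to decide. The 35 splits took each library as a separate unit, though replicate libraries of a clone may be technical. They therefore do not show that a response holds across clones.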

How the results depend on the processing

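The edgeR test, the stroma covariate and the list medians over the same members were added after the data had been examined. No gene or list call passed in the opposite direction. With TMM factors, however, the percent of called genes that were higher went from 53.2 to 47.4 for DoxRA, 69.9 to 48.6 for BMS, 56.4 to 49.8 for B2RA against BMP2 in H18, 60.5 to 47.0 for B2RA in the Zglp1 knockout, 67.2 to 49.7 for OESko_A11, 38.8 to 51.8 for the Zglp1 knockout against H18 under BMP2 and 45.6 to 50.3 for the Stra8 knockout against H18, and with edgeR from 81.1 to 47.6 for the BMS difference. Depth limits calls of low genes, because 1 read was worth up to 1.14 RPM, and groups of 2 limit calls of small changes. Counts stayed within 1.5 times in 20 of 20 comparisons with the stroma covariate, 18 with TMM factors, 17 with pseudocount 5, 16 with edgeR, 15 with array weights, 12 with only the groups compared and 6 with no filter. Of 1701 gene calls followed, 1647 were kept with TMM factors and 54 lost, 1522 and 179 with edgeR, and 1493 and 208 with only the groups compared. Of 167 list calls, 71 were kept with an estimated correlation and 96 lost. TMM factors shifted the median log2 change of DoxRA by -0.128, BMS by -0.248, the BMS difference by -0.172, B2RA in the Zglp1 knockout by -0.14, the Zglp1 knockout against H18 under BMP2 by 0.129, B2RA in the Stra8 knockout by -0.233 and OESko_A11 by -0.204. The causes were not tested, except that more genes are tested with no filter and fewer libraries set the spread with only the groups compared.

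For the SerumMinusWIN difference the count was 3 with pseudocount 0.5, 8 with pseudocount 5, 99 with no filter, 2 with TMM factors, 2 with array weights, 0 with only the groups compared and 0 with edgeR. For the BMS difference it was 273 with pseudocount 5, 408 with no filter, 260 with array weights, 77 with only the groups compared and 21 with edgeR. For BMP2 in H18 at day 3.5 it was 0 with pseudocount 0.5, with TMM factors and with array weights, and 5 with no filter, where RA gave 6 and B2RA 19. With no filter the counts were 6980 for DoxRA, 2591 for DoxRA against Dox, 3134 for BMS, 2377 for B2RA against BMP2 in H18, 511 and 1976 for BMP2 and B2RA in the Zglp1 knockout, 2433 for that knockout against H18 under BMP2, 3370 for B2RA in the Stra8 knockout and 3227 for OESko_A11. Array weights gave 826 for DoxRA against Dox and 994 for B2RA against BMP2 in H18. Only the groups compared gave 514 for DoxRA against Dox, 409 for B2RA against BMP2 in H18, 80 and 650 for BMP2 and B2RA in the Zglp1 knockout, 304 for the difference between knockouts and 1281 for that between OESko_A11 and OE_A2. B2RA in the Zglp1 knockout gave 644 with pseudocount 5. BMP2 there gave 38 in clone E5 alone and 80 with edgeR, and the difference between knockouts 273 with edgeR.

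Replicates share only a number, and a block term for it gave 5 genes for the SerumMinusWIN difference and 295 for the BMS difference, with 18 of 20 counts within 1.5 times. It kept all 1701 gene calls and added Stra8 for the BMS difference (adjusted p = 0.012), for the Zglp1 knockout against H18 under B2RA (0.035) and for OESko_A11 against OE_A2 (0.035), and of list calls 1 was lost and 4 gained. Libraries with the same number deviated together in some comparisons and not in others, with correlations from -0.192 to 0.516 (0.329 to 0.516 in H18 at day 3.5, 0.271 for BMS and 0.188 to 0.236 in the Stra8 knockout, but -0.048 for B2RA against BMP2 in H18). Groups held at most 2 numbers. No comparison with 3 or more pairs of groups had every correlation over 0.1, so the numbers were not taken as pairs. That rule could not judge H18 at day 3.5, where each comparison held 1 pair of groups, correlated over 0.1. The block term left those counts within 1.5 times.

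With each library left out in turn, a lone sample being assumed to vary like the other groups, counts ran from 0 to 0 for BMP2, 0 to 153 for RA and 0 to 23 for B2RA in H18 at day 3.5. They ran from 304 to 2094 for B2RA against BMP2 in H18, 608 to 1779 for the Zglp1 knockout against H18 under BMP2, 1374 to 1706 for Dox, 568 to 1493 for DoxRA against Dox, 1130 to 2263 for SerumMinusWINDox and 1109 to 1896 for BMSDox. The SerumMinusWIN difference ran from 0 to 47, the BMS difference from 8 to 208, BMP2 in the Zglp1 knockout from 74 to 191, the difference between knockouts from 476 to 1482 and OESko_A11 from 946 to 1518.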

Other observations

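The test of the chromosome hypothesis below had its prediction written before its result was seen. Without Dox, BMS against control medium in OE_A2 at day 9 lowered Stra8 from 332 ± 63 to 1.38 ± 0.354 RPM (limma log2 change -7.12 ± 0.69, adjusted p = 4.1e-13, n = 2), Rec8 by -2.33 ± 0.43 (adjusted p = 0.00026) and Meioc by -3.22 ± 0.65 (adjusted p = 0.0011). Of 21 meiotic prophase genes 5 fell (10 adjusted over the list alone; camera adjusted p = 2.6e-07, and 0.036 with an estimated correlation). Tags of the mCherry row were lower there too, at 69.7 ± 37.1 RPM with BMS against 284 ± 172 in control medium. The falls of Stra8 and the meiotic genes could therefore not be told apart from an effect of less transgene mRNA. The Nodal antagonists Lefty1 (-4.34 ± 0.62, adjusted p = 1.5e-06) and Lefty2 (-4.24 ± 0.66, adjusted p = 1.4e-05) fell. Of 6 RA response genes 3 fell (3 adjusted over the list alone), among them the RA-binding protein genes Crabp1 (-2.10 ± 0.53) and Crabp2 (-1.87 ± 0.49). Ddit3, a stress-induced transcription factor, rose by 1.81 ± 0.47, the 1 of 11 members of the integrated stress response that passed (2 adjusted over the list alone; camera adjusted p = 6e-07, and 0.0072 with an estimated correlation). In all 222 genes were called, 49 higher and 173 lower. SerumMinusWIN against control medium without Dox called 2 genes. Uninduced OESko_A11 against uninduced OE_A2 called 44 genes, 34 higher and 10 lower, with Stra8 at -3.83 ± 0.69 (adjusted p = 0.0013), Tcl1 at 1.97 and Tdh at 1.60.

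Metabolic and cell cycle lists also moved at day 9. Cholesterol synthesis genes fell in 7 of 19 with Dox in OE_A2 (camera adjusted p = 8.8e-05, and 0.036 with an estimated correlation) and in 7 of 19 with DoxRA in OESko_A11 (2.2e-08 and 0.0031), and 13 of 19 were higher in the Zglp1 knockout than in H18 under B2RA (1.1e-05 and 0.034). Genes of DNA methylation fell in 4 of 9 with Dox, including Dnmt3l (-3.82) and Dnmt3b (-2.76) (0.0013 and 0.036). DNA replication genes fell in 6 of 20 with B2RA against BMP2 in H18 (5.1e-05 and 0.028), and G2 and M phase genes in 6 of 20 with Dox, where 1 rose (0.0021 and 0.18). Genes of p53 and apoptosis were higher in 9 of 12 in the Zglp1 knockout against H18 under B2RA (4.4e-05 and 0.034). Gonadal soma genes could be tested in 5 comparisons, none of which passed (0.084 in the Stra8 knockout with B2RA, the lowest).

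Levels along chromosomes were compared under the hypothesis that a clone carried an extra or missing chromosome. Of 140 combinations of line and chromosome the largest median was 0.448, on X in Sko_F6, with H18 at 0.399, Sko_B6 at -0.228 and OESko_A11 at -0.204. The prediction was met, which may reflect copy number of X or its state of activity, and the test could not separate them. Of 210 X genes, 86.7 percent lay above 0 in H18 and 91.4 percent in Sko_F6, against 13.8 percent in Sko_B6. Xist stood at no more than 8.88 RPM in any line.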
